A study of Paxillus involutus with 12 samples.

How the data were processed

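Expression was measured in mycelium of the ectomycorrhizal basidiomycete Paxillus involutus on 12 subarrays of a single 12-plex NimbleGen chip, a 1-colour (Cy3) oligonucleotide array. Per the labels' protocols, the fungus was grown axenically on glass beads in a minimal medium with ammonium at a C/N ratio of 3, after a pre-culture and a day without nitrogen, and RNA was taken at days 2, 6, 8 and 13. Each replicate was a separate pool of 2 cultures, with 3 replicates per day, so the spread between arrays of a day includes differences between cultures. Days and replicate numbers were taken from the sample titles.

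The deposited values are log2 expression values made by the authors with RMA over the whole array, per the file headers and the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a sequence by median polish. Its version and any further filter are not given in the sources used here. The log2 scale was inferred from the range of the deposited values, 2.81 to 15.6, which is that of a 16-bit scanner signal on a log2 scale. The number of probe pairs per sequence, a further deposited column, was 10 for 12203 of the 12214 sequences and between 2 and 10 for the other 11. A random-sequence control feature summarised from 10000 probes served as the measure of background. The series-wide value table held the same log2 values as the deposited per-array files in all 146568 cells, with a largest difference of 0. RMA forces the arrays to nearly the same distribution, so a change in total messenger RNA per mass of mycelium is not visible and every change is relative to the other sequences on the array.

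Sequences carry only numbers (paxillus_1 to paxillus_13654, not all of them used here). The gene information column was empty in every file, and none of the 12214 IDs occurred among the 18033 genes of the reference table of assembly GCA_000827475.1 v1.0, so the files do not pair sequences with gene names. The 29 gene lists fixed in advance (autophagy, proteases, nitrogen assimilation, ribosome and others) could therefore not be matched and none was tested. The counts below are of array sequences, several of which can stem from the same gene.

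The log2 values of all 12 arrays were fitted in 1 linear model with a mean per day in limma 3.58.1 (R 4.3.3, lmFit, contrasts.fit and eBayes), without a replicate block. The fit had 8 residual degrees of freedom and a prior of 4.23. P-values were adjusted by the Benjamini-Hochberg method over the 12214 sequences within each comparison, and a sequence was called changed at an adjusted p under 0.05. Counts with an additional fold of at least 2 are given beside them. A moderated F-test over the 4 day means gave the sequences that changed at all, and each of these was assigned the day of its highest and of its lowest mean. Control features were left out of the tests. No filter on dim sequences was applied. Day means are given ± SD over 3 arrays, and log2 differences ± the standard error of the limma fit. The number of arrays limits the precision. The median standard error of a difference between days was 0.100 on the log2 scale.

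The tests of the 6 comparisons, the F-test, the overlap, the rule for named sequences and most alternatives were fixed before the data were examined. The counts at 4-fold and 8-fold and the opposite directions were chosen after exploratory fits of these data. So were the runs of consecutive sequences with similar level and profile, with their limits. The tests of explanations other than the splits of the arrays were also chosen then. With no gene names, the rule gives the 2 largest rises and the 2 largest falls per comparison, among called sequences whose 3 arrays of one day all lay above or all below the 3 of the other day. The overlap between comparisons that share the day 2 arrays was set against 20 simulations of unchanged days and against the overlap of independent lists. The simulations gave each sequence the same spread on every day.

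The fit was tested on simulated data with the real means and residual spreads of 12214 sequences, of which 50 each were changed at day 13 by 0.25, 0.5, 1 and 2 on the log2 scale. For day 13 against day 2, 100% of the 50 sequences changed by 2 were recovered, 94% of those changed by 1, 62% of those changed by 0.5 and 6% of those changed by 0.25. Of the 12014 unchanged sequences, 7 were called. Far more sequences were called in the data than were changed here, which makes the adjusted threshold less strict there. The simulated noise was independent and had the same spread on every day. The shares recovered and falsely called therefore do not carry over to the real comparisons.

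Alternatives were median centring, quantile normalization, removal of sequences at the control level, eBayes with trend and robust settings, array weights, the replicate number as a block, a fit of only the 6 arrays compared, a threshold of 0.01, a test against a minimum fold of 1.5 (limma treat), the exchange of days 6 and 8, and leaving out each array in turn. An offset of 50 on the linear scale and the joint removal of 2 arrays were added after seeing the data. The averaging of consecutive sequences with similar level and profile was added then too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.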

Results

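The transcriptome of carbon-starved Paxillus involutus was followed over 4 harvests, at days 2, 6, 8 and 13, with 3 arrays per day and 12214 sequences per array. Day 2 is the earliest harvest and serves as the baseline. The series asks how expression changes as the fungus runs out of carbon. The samples include no carbon-supplied cultures of the same ages, so starvation cannot be told apart from culture age in any comparison. The array medians lay between 11.35 and 11.38 on the log2 scale, and the random-sequence control between 4.49 and 4.70. On all 12 arrays, 11524 sequences were at least 2-fold above that array's own control, and 278 sequences were at or below it on every array. Arrays of the same day correlated at r = 0.989 to 0.998 across sequences. The median SD over the 3 arrays was 0.129 at day 2, 0.0790 at day 6, 0.0771 at day 8 and 0.139 at day 13. The descriptions of 6 samples carry 2 position numbers that disagree. Samples titled day 6 are given as subarrays 7 to 9 and as arrays 4 to 6, and samples titled day 8 as subarrays 4 to 6 and as arrays 7 to 9. The titles were followed throughout, and the comparison of day 13 with day 2 does not depend on this. The 3 arrays of each day lie at consecutive array numbers, so a position effect and a day effect cannot be told apart in any comparison.

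Arrays separated by harvest day. The first principal component held 58.1% of the variance and placed the days in order of time, with mean scores of -36.5 at day 2, -14.4 at day 6, 1.9 at day 8 and 48.9 at day 13, and no overlap between days. This is also the order of the array numbers. The second component held 25.1% and set days 6 and 8, with mean scores of -14.6 and -25.0, apart from days 2 and 13, with 24.6 and 15.0.

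**Figure D1:**
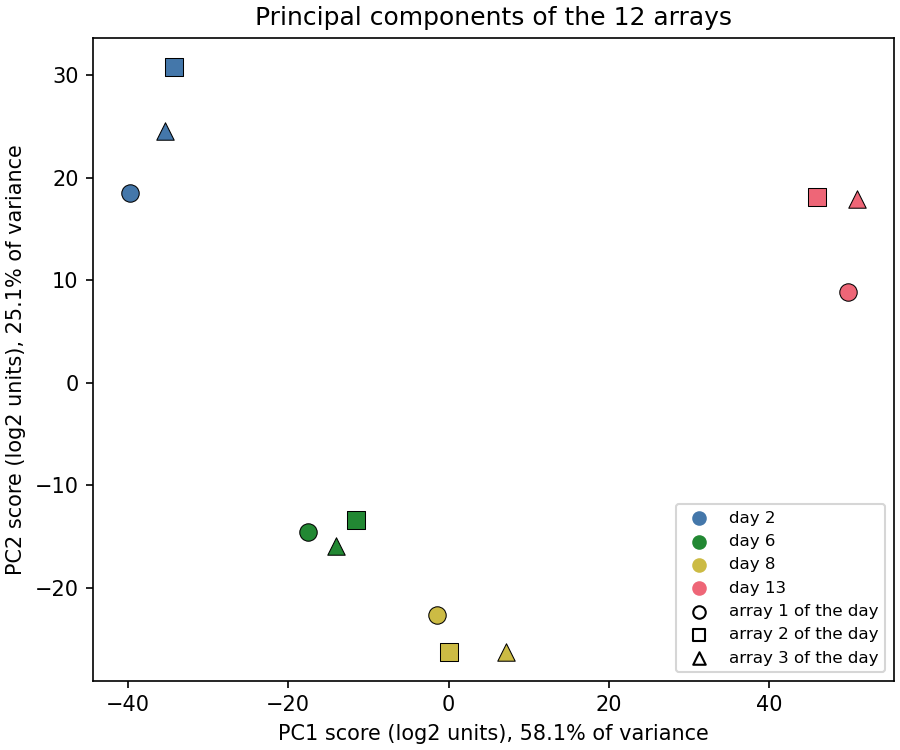
Scores of the 12 arrays on the first (x axis) and second (y axis) principal components of the log2 values, with the share of variance on each axis; colour gives the day and symbol the replicate number. Days follow each other along the first component, from a mean of -36.5 at day 2 to 48.9 at day 13, and days 6 and 8 lie lowest on the second.

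Across the 4 days, 10042 of 12214 sequences changed (82.2%, limma moderated F-test, adjusted p under 0.05), and 2677 of them spanned at least 2-fold between their highest and lowest day. The extremes of expression fell mostly on the earliest and the latest harvest. Day 2 held the highest mean of 3207 changed sequences and the lowest of 3517, and day 13 the highest of 3377 and the lowest of 3372. Day 8 held the highest of 2150 and the lowest of 1836, and day 6 the highest of only 1308 and the lowest of 1317. With days 6 and 8 exchanged, the counts of these 2 days change places here and in the classes.

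The 2 largest classes ran from one end of the time course to the other. The class highest at day 2 and lowest at day 13 had 1894 sequences, with a median range of 0.87 on the log2 scale. Its counterpart, lowest at day 2 and highest at day 13, had 1758 sequences and a median range of 0.78. Next came sequences with an extreme mean at day 8 and the other at day 2; whether they turned after day 8 was not tested for each class. Of these, 1306 were lowest at day 2 and highest at day 8, and 1030 were highest at day 2 and lowest at day 8. A further group had an extreme mean at day 6: 915 sequences had their lowest mean at day 6 and their highest at day 13, and 753 the reverse. Between days 8 and 13, 725 were highest at day 8 and lowest at day 13, and 704 the reverse. Sequences with their highest and lowest mean on days 6 and 8 were rare, with 119 lowest at day 6 and highest at day 8, and 102 the other way round.

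**Figure D2:**
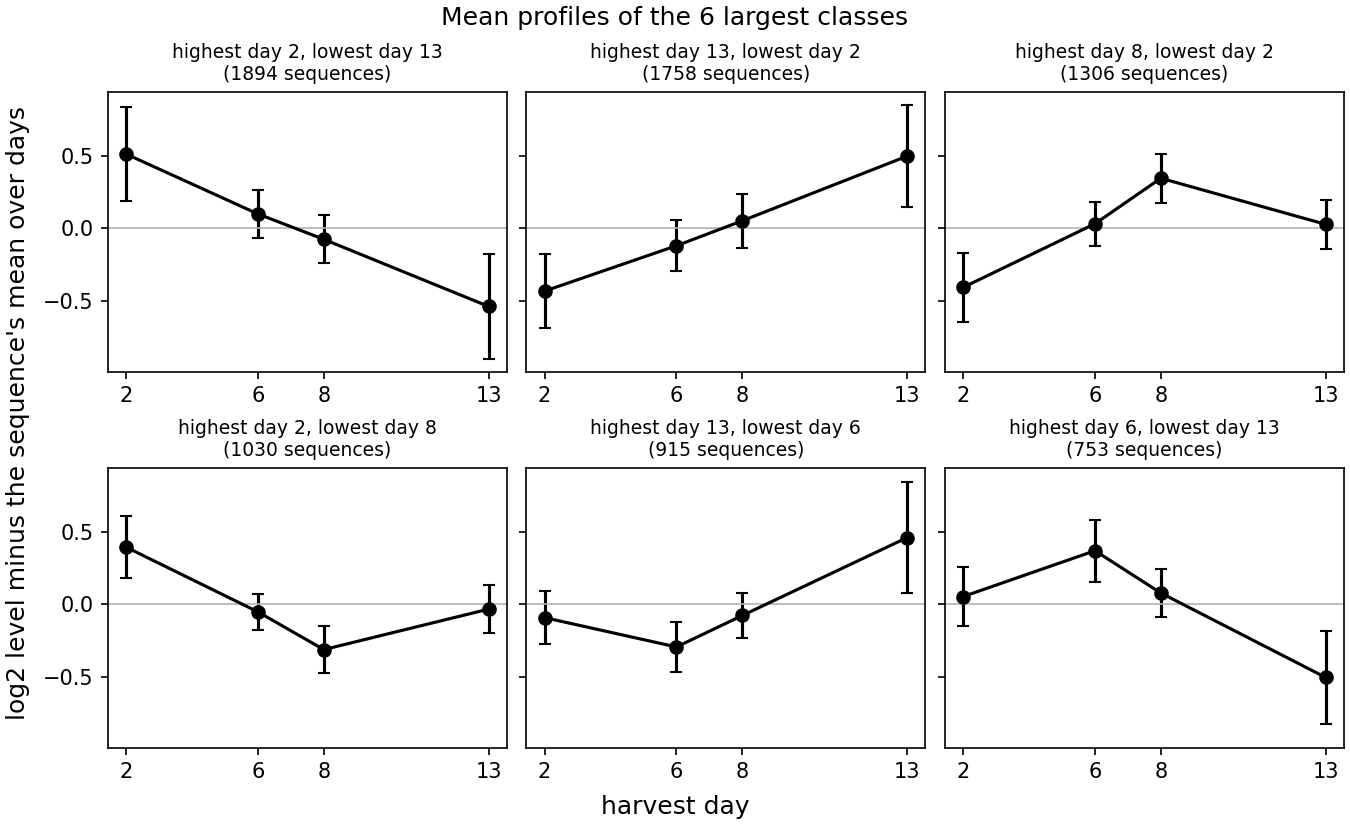
Mean profile of the 6 largest classes of changed sequences, defined by the day of the highest and the lowest mean; the x axis is the harvest day, the y axis the log2 level minus the sequence's own mean over days, and bars are the SD between sequences. The 1894 sequences highest at day 2 and lowest at day 13 averaged 0.52 above their mean at day 2 and -0.54 at day 13.

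The comparison of day 13 with day 2 sets the latest harvest against the earliest, and it gave the most changes of at least 2-fold. Of 12214 sequences, 4201 rose and 3839 fell, together 65.8%. At least 2-fold, 917 rose and 987 fell. At least 8-fold, 26 rose and 24 fell. The rises with the largest fold were paxillus_4061 and paxillus_4062. paxillus_4061 went from 9.65 ± 0.18 (SD, n = 3) at day 2 to 14.07 ± 0.40 at day 13, 21.4-fold (log2 difference 4.42 ± 0.35, limma adjusted p = 2.85e-07), and paxillus_4062 from 9.77 ± 0.19 to 14.13 ± 0.42, 20.4-fold. These 2 belong to a run of 4 consecutive sequence numbers with nearly the same values on every array, so they are not counted here as separate genes. At day 6 their means were 10.49 ± 0.93 and 10.56 ± 0.71, with a wide spread between arrays, and at day 8 they were 9.85 ± 0.20 and 9.97 ± 0.22. The deepest falls were those of paxillus_9783 and paxillus_383. paxillus_9783 dropped from 12.90 ± 0.11 to 7.11 ± 0.32, 55.3-fold lower (log2 difference -5.79 ± 0.29, limma adjusted p = 8.97e-09), through 10.90 ± 0.39 at day 6 and 10.09 ± 0.70 at day 8. paxillus_383 dropped from 14.01 ± 0.11 to 9.50 ± 0.43, 22.7-fold lower, through 13.26 ± 0.22 and 12.51 ± 0.15. A minimum fold of 1.5 in the test itself (limma treat) left 2311 sequences. Without a minimum fold the order of the comparisons depended on the fit: day 8 against day 2 gave 8667 calls with array weights, where day 13 against day 2 gave 8020, and 7128 against 6927 in fits of only the 6 arrays compared.

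**Figure D3:**
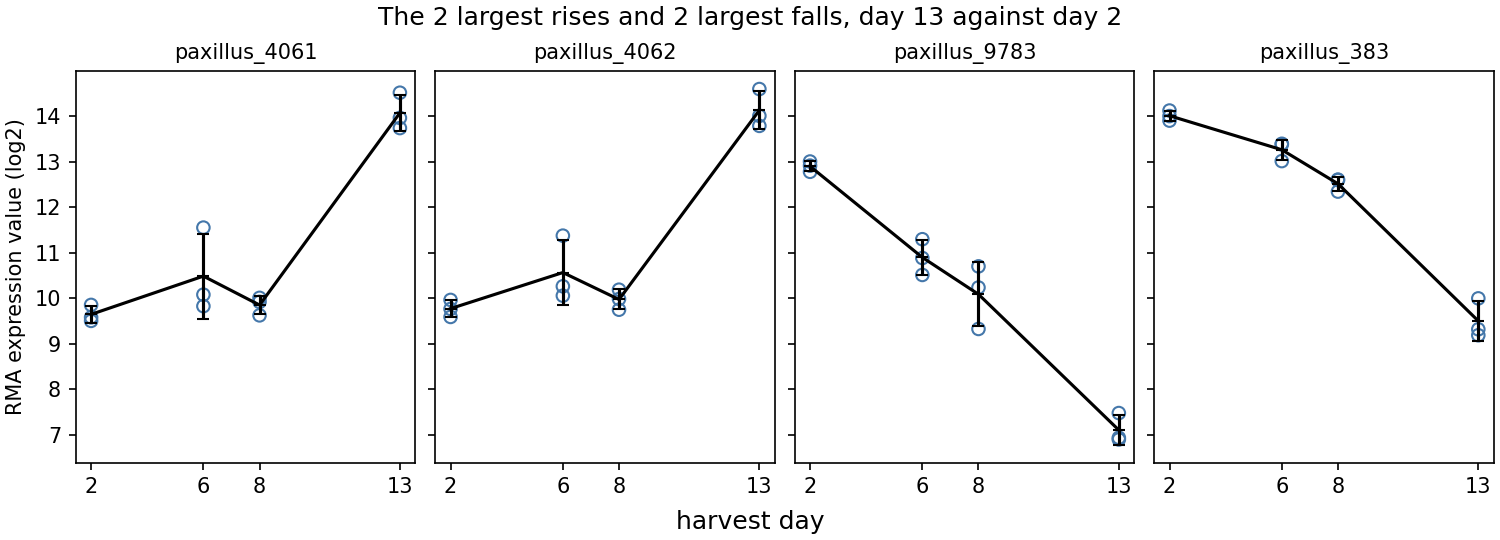
RMA expression values (y axis, log2) of 4 sequences by harvest day (x axis); open circles are single arrays, and the line joins day means with SD over 3 arrays. The 2 rising sequences stay near 10 at day 8 and exceed 13 on every day 13 array, while paxillus_9783 and paxillus_383 fall at every harvest mean.

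By day 6, 5635 sequences differed from day 2, with 2808 higher and 2827 lower, but few of them by much: 282 were at least 2-fold higher and 152 at least 2-fold lower. paxillus_12204 rose from 7.97 ± 0.48 (SD, n = 3) to 10.46 ± 0.14, 5.62-fold, and stayed at 10.05 ± 0.25 and 10.17 ± 0.34 at days 8 and 13. paxillus_3111 rose from 9.46 ± 0.88 to 11.88 ± 0.14, 5.37-fold, from a baseline that varied widely between the day 2 arrays. paxillus_1460 fell from 12.73 ± 0.45 to 9.70 ± 0.12, 8.20-fold lower (log2 difference -3.03 ± 0.17, limma adjusted p = 7.15e-07), and remained at 9.41 ± 0.01 and 9.38 ± 0.07 afterwards. paxillus_13188 fell from 9.40 ± 0.90 to 6.62 ± 0.13, 6.91-fold lower; it rests on only 2 probe pairs, and its log2 difference was -2.12 with array weights, against -2.79. With a minimum fold of 1.5 in the test, 203 sequences were left.

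By day 8, 7256 sequences differed from day 2, with 3769 higher and 3487 lower, of which 511 and 501 by at least 2-fold. paxillus_12524 rose from 7.24 ± 0.29 (SD, n = 3) through 8.76 ± 0.10 at day 6 to 10.13 ± 0.15 at day 8, 7.42-fold over day 2 (log2 difference 2.89 ± 0.15, limma adjusted p = 8.58e-08). paxillus_13167 rose from 8.19 ± 0.61 to 10.88 ± 0.33, 6.44-fold. paxillus_1038 fell from 12.83 ± 0.07 through 11.37 ± 0.18 to 9.42 ± 0.15, 10.6-fold lower, and paxillus_1460 was 9.97-fold lower. With a minimum fold of 1.5 in the test, 1202 sequences were left, and with days 6 and 8 exchanged the counts and values of these 2 comparisons change places.

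The step from day 6 to day 8 gave the fewest changes of at least 2-fold. In all, 1741 sequences rose and 1417 fell, and at least 2-fold only 36 rose and 43 fell. paxillus_7280 rose 3.37-fold, from 10.33 ± 0.16 (SD, n = 3) to 12.08 ± 0.25, on a course from 9.64 ± 0.24 at day 2 to 13.56 ± 0.17 at day 13. paxillus_5896 rose 3.23-fold, from 10.30 ± 0.29 to 11.99 ± 0.30, and reached 14.22 ± 0.21 at day 13. paxillus_394 fell 5.19-fold, from 11.73 ± 1.32 to 9.36 ± 0.72, with a wide spread between arrays (log2 difference -2.37 ± 0.54, limma adjusted p = 8.06e-03). Without day 6 array 3 its log2 difference was -3.13. It missed the threshold with a minimum fold of 1.5 in the test (limma treat adjusted p = 0.639). paxillus_8111 fell 4.20-fold, from 13.86 ± 0.14 to 11.79 ± 0.48. The total of 3158 changed sequences moved most with the setting. It was 5385 when only the 6 arrays of these 2 days, which vary less than those of days 2 and 13, set the spread, above the 5227 of day 6 against day 2 in such a fit, and it was 1751, 1850 or 1520 without day 6 array 1, day 6 array 2 or day 8 array 3, and 10 with a minimum fold of 1.5 in the test. An exchange of days 6 and 8 would turn every direction in this comparison.

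Between day 8 and day 13, 3148 sequences rose and 3461 fell, and at least 2-fold 437 rose and 447 fell. At least 8-fold, rises outnumbered falls: 24 sequences rose and 1 fell. paxillus_10215 stood at 10.11 ± 0.07, 10.12 ± 0.41 and 10.04 ± 0.16 (SD, n = 3) at days 2, 6 and 8, and at 14.30 ± 0.07 at day 13, 19.1-fold over day 8 (log2 difference 4.26 ± 0.16, limma adjusted p = 8.07e-09). paxillus_9608 went from 8.79 ± 0.07 at day 8 to 13.04 ± 0.31, 18.9-fold. The deepest falls were again those of paxillus_383, 8.06-fold lower than at day 8, and paxillus_9783, 7.89-fold lower. Day 13 against day 6 gave 3613 rises and 3530 falls, with 554 and 679 at least 2-fold and 25 and 9 at least 8-fold, and the same 4 sequences led it: paxillus_9608 rose 19.2-fold and paxillus_10215 18.1-fold, while paxillus_9783 fell 13.8-fold and paxillus_383 13.5-fold. With a minimum fold of 1.5 in the test, 984 and 1474 sequences were left in these comparisons, and with days 6 and 8 exchanged their values change places.

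**Figure D4:**
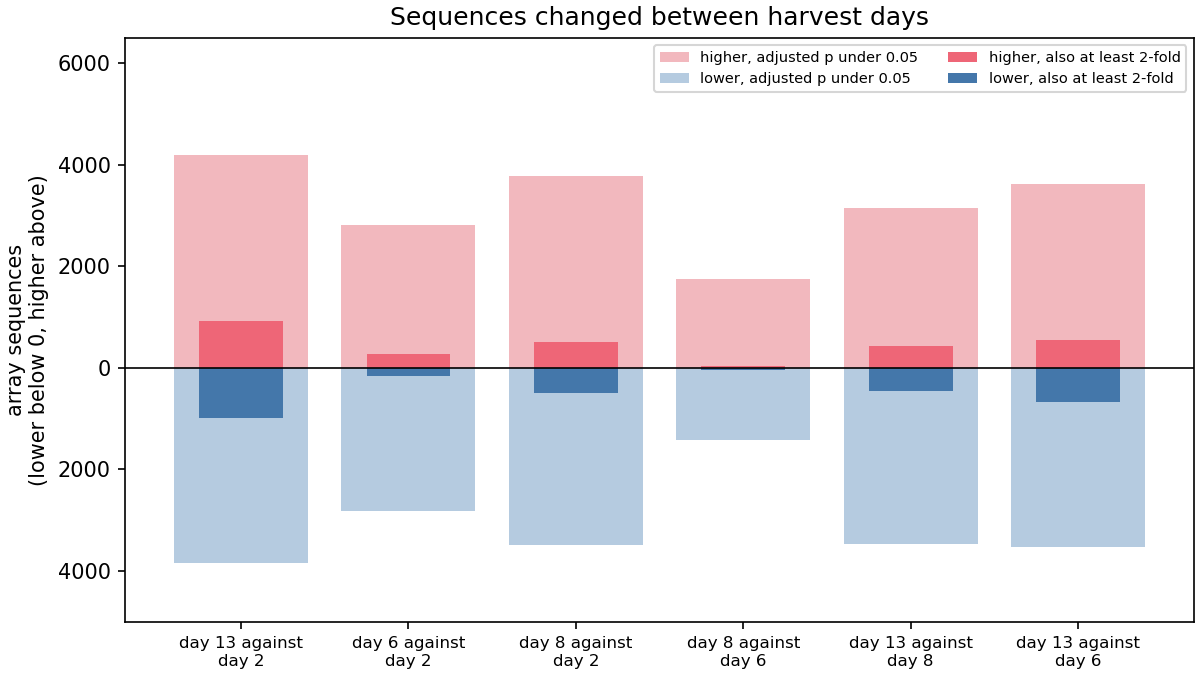
Number of sequences higher (above 0) and lower (below 0) in each comparison of harvest days (x axis); wide pale bars count sequences with an adjusted p under 0.05 and narrow dark bars those also changed at least 2-fold. Day 13 against day 2 has the tallest bars, with 4201 higher and 3839 lower, and day 8 against day 6 the shortest, with 1741 and 1417.

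Changes against day 2 were shared between harvests. At all 3 later days, 1619 sequences were higher than at day 2 and 1844 lower, together 3463, where independent lists of these sizes would share 551.7. The comparisons use the same day 2 arrays, and simulated unchanged days shared 0 calls with each other in 20 simulations. Unchanged days give almost no calls, so this 0 does not show how much the shared arrays add where real changes exist. Across sequences, the log2 changes at days 6 and 8 correlated at r = 0.857, where the shared day 2 arrays alone gave 0.501 in the simulations. The covariance was 0.216 against a simulated 0.0085. For days 6 and 13 the values were r = 0.568 and a covariance of 0.194, and for days 8 and 13 they were r = 0.679 and 0.304, with simulated values of 0.502 and 0.499 for r and again 0.0085 for the covariance. The simulations gave each sequence the same spread on every day. The median SD was larger at day 2, 0.129, than at days 6 and 8, 0.0790 and 0.0771. A larger day 2 spread raises what the shared arrays give, so the simulated r and covariance can be too low. The r of 0.568 for days 6 and 13 can thus not be read as above the shared part. The covariances can be read further, since the upper quartile of the SD at day 2 was only 0.198. Covariances of 0.194, 0.216 and 0.304 against 0.0085 argue against the spread between day 2 arrays as their only source. An error common to all 3 day 2 arrays does not show in that spread. Sequences are not independent replicates, and with 3 day 2 arrays the baseline could not be split into parts of 2 arrays each, so part of the excess may come from the shared arrays. A minority went the opposite way. Compared with day 2, 221 sequences were higher at day 6 and lower at day 13, and 226 were lower at day 6 and higher at day 13, with a called difference between days 6 and 13 in each. For days 8 and 13 the numbers were 220 and 270. Most of these changes were small: at least 2-fold on both days, 5 and 1 sequences were left for days 6 and 13 and 2 and 6 for days 8 and 13.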

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

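The tests of array position, scaling and repeated sequences as explanations were chosen after the result was seen. Sequences that moved in opposite directions at 2 harvests, relative to day 2, drew attention because the difference between the 2 harvests was itself past the limma threshold: 447 sequences for days 6 and 13, 490 for days 8 and 13 and 20 for days 6 and 8. Independent lists of the same sizes would hold 1854.9, 2384.0 and 1674.0 opposite pairs. The 20 fell to 9, 13, 8, 11 or 10 without day 2 array 3, day 6 array 1, day 6 array 2, day 8 array 2 or day 8 array 3, and rose to 106 with array weights. At a threshold of 0.01 the 490 fell to 239 and the 20 to 1, and with a minimum fold of 1.5 in the test 4 and 0 were left.

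For the 447 sequences of days 6 and 13, repeated counting within runs of consecutive numbers adds little, since 434 were left when the runs were averaged. The runs hold 555 sequences, found by level and profile alone. Repeats at other numbers, or with profiles too noisy to be linked, were not averaged, so repeated counting beyond the runs stays open. A uniform shift of whole arrays left in the deposited values is argued against. The array medians ranged over 0.0245 on the log2 scale. The smallest called changes from day 2 were larger, 0.159 at day 6 and 0.152 at day 13. The count did not fall when each array was centred on its median or the values were quantile normalized. A shift that RMA had removed stays open, since RMA values show no change common to all sequences. The less frequent direction held 49.4% of the 447. This share cannot decide, because shifts of the same sign at both days can add to both directions. The position on the chip stays open too: the 3 arrays of each of the 4 days lie at consecutive array numbers, so a position effect and a day effect cannot be told apart. A response to the duration of starvation, the factor the design names, stays open as well and has no further test here. The count was 178 at a threshold of 0.01, 748 with array weights and 0 with a minimum fold of 1.5 in the test. Most of these changes were small, but 5 sequences higher at day 6 and 1 lower at day 6 changed at least 2-fold on both days.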

How the results depend on the processing

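The offset, the averaging of consecutive sequences with similar level and profile and the joint removal of 2 arrays were chosen after seeing the data. Most counts kept their size: 173 of 187 values of the main counts under settings other than leaving out an array lay within 1.5 times the original, as did 93 of 96 with 1 array left out. The 187 include values that could not move. The series-wide value table holds the same values, and the exchange of days 6 and 8 does not touch day 13 against day 2. A test against a minimum fold of 1.5 is stricter by construction and left 2311 sequences for day 13 against day 2, 203 for day 6 against day 2, 1202 for day 8 against day 2, 10 for day 8 against day 6, 984 for day 13 against day 8, 1474 for day 13 against day 6, and 149 changed the same way at all 3 later days. A threshold of 0.01 left 3749 for day 6 against day 2, 1360 for day 8 against day 6 and 2287 of the shared sequences. Day 8 against day 6 gave 5787 with array weights and 5385 in a fit of those 6 arrays, which contain all 3158 and 3156 of the original calls; the cause was not tested beyond the smaller SD of these days. Leaving out 1 array gave 1520 to 2484 there, 7606 to 7947 for day 13 against day 2, 4523 to 5595 for day 6 against day 2 and 6354 to 7072 for day 8 against day 2. With days 6 and 8 exchanged, day 6 against day 2 had 1012 sequences changed at least 2-fold and day 8 against day 2 had 434, and between days 8 and 6 paxillus_7280 became -1.75, paxillus_5896 -1.69, paxillus_394 2.37 and paxillus_8111 2.07, by construction. Of 480 other values for the named sequences, 475 kept direction and call, and 4 were these reversals. paxillus_394 between days 8 and 6 missed the threshold with a minimum fold of 1.5 (limma treat adjusted p = 0.639). The named sequences were chosen for their large changes in these same arrays. The 480 also include values that could not move, so most were bound to hold. The planned offset for linear values did not apply to log2 values and was run on back-transformed values instead, and the gene list alternatives were not run because no list could be matched.

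Replicate numbers did not pair the arrays: over the 18 pairs with the same number the deviations from the day means correlated at -0.30 to 0.63, only 5 pairs were over 0.1, and 1 of 12 arrays correlated best with its own number on all other days. With the replicate number as a block, the counts were 7985 for day 13 against day 2, 5536 for day 6, 7216 for day 8, and 3099, 6540 and 7063 for day 8 against day 6, day 13 against day 8 and day 13 against day 6.

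Only 10 splits of 6 arrays exist, too few for a share under 0.05. In each comparison 1 split, the real one, gave the most calls. The highest other split gave 195 for day 13 against day 2, where the real one gave 8040, and 0 for each of the other comparisons. For the F-test, 1 of 100 splits of the 12 arrays, the real one, reached 10042 and the highest other reached 3761. For sequences shared by all 3 later days, 1 of 100 reached 3463 and the highest other 0. At 1 of 100 splits, these values argue against a chance division of the arrays for both counts. The 0 does not measure how much sharing to expect, since splits that mix the days gave no shared calls at all. A part of the sharing that comes from the common day 2 arrays is not excluded.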

Other observations

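Apart from the splits of 6 arrays, the tests in this part were chosen after the results were seen. The exchange of days 6 and 8 and leaving out single arrays were planned as settings. The step from day 8 to day 13 held a group of late, strong rises. Of the 24 sequences at least 8-fold higher at day 13 than at day 8, 10 had no call in any comparison among days 2, 6 and 8. The rest had such a call. Of all 6609 sequences called between days 8 and 13, 1774 had none, so an earlier course without calls was not particular to this group. The median level of the 24 was 9.97 at day 8 and 14.01 at day 13. Only 1 sequence was at least 8-fold lower. Leaving out any array of the 2 days gave 24 to 28 higher and 0 to 2 lower. Averaging runs of consecutive sequences with similar level and profile gave 20 and 1. At least 4-fold, 83 were higher and 28 lower. At 8-fold, day 13 against day 6 gave 25 higher and 9 lower, the values this step would take with days 6 and 8 exchanged, and day 13 against day 2 gave 26 and 24.

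Changes between day 13 and day 2 reached all levels of expression. In 4 groups of equal size by mean level, from dimmest to brightest, 17.2%, 16.9%, 14.8% and 13.5% of sequences changed at least 2-fold, while 56.1%, 69.2%, 68.6% and 69.5% were called with no minimum fold. With the control as the limit, 1 sequence switched from background to expression. It was at or below the control on every day 2 array and at least 2-fold above it on every day 13 array. The reverse held for 0. Only 391 sequences lay at or below the control on every day 2 array, and 357 on every day 13 array. Few could therefore count as switched, and a switch from a higher background level would be missed.

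The array's own numbering carries structure. Among 11427 pairs of consecutive numbers, 292 had mean levels within 0.5 and a profile correlation over 0.95 across the 12 arrays, and 0 of 100 shuffles of the numbers gave as many (highest 24). Of these pairs, 288 lie at numbers up to 7000 and 4 above. The 624 sequences with the highest numbers had a median level of 4.86, and 45.7% of them had a mean at or below the control limit of 4.68. It is a hypothesis that such pairs are variants of one transcript; the sequences that could decide it were not used here.

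Day 2 array 2 and day 13 array 2 deviated from their day means in the same way (r = 0.633 across sequences). Day 2 array 1 deviated in the opposite way to day 13 array 2 (r = -0.622). The deviations of the arrays of a day cancel in sum, so these correlations are not separate observations. Any shift common to sequences of similar level that was left in the deposited values was small. Each array's median deviations in 10 bins of level were at most 0.0423 and 0.0354. RMA brings the arrays to a common distribution, so small medians were likely in advance. With so little to remove, r could hardly change. It was 0.636 afterwards, which decides nothing about normalization. By contrast, 48 sequences deviated by over 0.5 in the same direction on both second arrays, and 0 in opposite directions. Other effects of normalization were not tested. Unequal progress of the day 2 cultures stays open: day 2 array 1 minus array 2 correlated at r = 0.397 with day 6 minus day 2 array 3, which shares no array with it, but day 13 array 2 minus the other day 13 arrays correlated at -0.39 with the same difference, which progress at day 2 cannot give. For day 13, array 3 minus array 2 correlated at -0.25 with day 8 minus array 1, and array 1 minus array 2 at -0.07 with day 8 minus array 3, which leaves unequal progress between days 8 and 13 open. A split that put both second arrays and day 2 array 3 against the others called 195 sequences, and without both second arrays together no main count moved by over 1.5 times.

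The disagreement between the 2 position numbers of days 6 and 8 raises the question of whether the titles were exchanged. Arrays titled day 8 scored 16.3 higher on the first principal component than those titled day 6, on the side of day 13, which is the order of the titles. In the order of the titles 124 sequences rose and 205 fell at each of the 3 steps, and with the days exchanged 2 and 1 did. The 124 were 65, 68 or 72 without day 6 array 1, 2 or 3 and 74, 77 or 75 without day 8 array 1, 2 or 3, and the 205 were 96, 121, 132 or 99 without day 6 array 1 or 2 or day 8 array 2 or 3. These values go with the order of the titles, which is also the order of the array numbers. The step counts and the component scores both reflect the place of day 8 between day 6 and day 13, so they are not separate support. Expression need not move steadily with time, so the values cannot decide and an exchange is not excluded. The image identifier in each array's data carries the array number, not the subarray number.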
